A study of Mus musculus with 4 samples.

How the data were processed

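Gene expression was measured on 4 Agilent mouse 1-colour arrays of cells sorted from mouse bone marrow (strain C57BL6/J, 7 weeks of age per the labels). LSK cells are the lineage-negative, Sca-1-positive, c-kit-positive cells that hold the blood stem and early progenitor cells. The CD45-negative cells were sorted as marrow stromal cells, called niche cells in the labels. Ptprc, the gene of CD45, was nonetheless above background in this sort at both days, and red cell genes were bright in it at day 0. Each population was taken at day 0 from healthy mice and at day 10 from recipient mice that had been given 700 cGy of radiation and 30000 LSK cells. Per the labels, the donors carried the CD45.2 form and the recipients the CD45.1 form of the pan-leukocyte antigen CD45, and the stromal cells were sorted as CD45.1-negative; elsewhere the labels call the same cells CD45-negative without naming a form, so which antibody was used is not certain. Each of the 4 groups has 1 array, so no comparison has a test or a standard error, and every difference is a difference between 2 arrays. A model with population and day as terms would leave 1 residual degree of freedom for a day effect shared by both populations; it was not run, since the question is what each population does. The sex of the mice is not stated in the labels.

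Per the labels, 500 ng of total RNA from each sample was primed with oligo-dT and labelled with Cy3. The authors processed the scans with Agilent Feature Extraction 10.5.1.1. Per the file headers, the spot signals are fluorescence intensity values: a raw mean and local background for each spot, and a processed signal with the background subtracted and spatial trends removed. The deposited spot files also hold flags for detection, saturation and outlier spots and a control type, which are neither signals nor ratios (unit: other). The deposited series table holds log2 values, which the authors shifted so that the 75th percentile of each array lies near 0. For at least 99.977% of the probes on each array these equal the log2 processed signal minus 1 constant, within 0.001 log2 units. The design's genomic build is mm9 per the file headers; no coordinates are given here. Gene names came from the spot files and were updated through RefSeq accessions, which matched 28136 of 40628 gene probes (69.3%) and renamed 2886 genes. Genes are identified here by symbol.

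Control spots and outlier spots were removed. The processed signal was log2-transformed and averaged over the spots of a probe, and the array's 75th percentile was subtracted. All levels are therefore log2 values relative to the 75th percentile of their array, and a difference is day 10 minus day 0, or LSK minus CD45-negative. Each gene was represented by its probe with the highest mean over the 4 arrays. Probes for noncoding transcripts, 20679 of 61307, were kept apart from the 29411 named genes. A fold was taken as measured where the probe was well above background, by the scanner software's flag, on both arrays. Where it was above background on 1 array and no probe of the gene was on the other, the fold is a lower bound against the lowest level called above background there. These lowest levels were -3.95 and -4.12 for LSK cells at day 0 and day 10, and -3.15 and -4.24 for CD45-negative cells. A difference of at least 2-fold was counted; this is a size, not a test.

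The 45 gene lists, 18 of cell type markers and 27 of processes, hold 962 different genes, of which 957 are on the array. A list is summarised by the median difference over its genes above background on at least 1 of the arrays compared. Its percentile is its place among 10000 random lists of equal size matched on mean expression in 20 bins. A list among the outermost 2.5% at either end is called outside the random range. They describe these arrays and are not p-values, since genes of a list are not independent.

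Named genes follow a rule. For each comparison of days it takes the 10 largest differences each way among genes above background and unsaturated on both arrays. These also had to be at least 2-fold the same way under the normexp, quantile, cyclic loess and mean-of-probes alternatives, and clone or predicted names were left out. It adds the 3 largest bounds each way and up to 4 members of each described list with the largest difference. Ptprc, Kit, Ly6a, Mki67, Cdkn1a, Cdkn1c, Cxcl12, Kitl, Angpt1, Vcam1 and Spp1 are given always. For LSK against CD45-negative cells it takes the 5 largest differences each way at each day. The lists, this rule, the 2-fold threshold and the alternatives were fixed before the data were examined, except where stated.

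The alternatives were normexp background correction of the raw signals (offset 50), quantile and cyclic loess normalization, a median shift, the 75th percentile of probes detected on all arrays, a shift by housekeeping genes, and the deposited series table. Others used no detection filter, detection on at least 1 of the arrays compared or on all 4 arrays, the mean over a gene's probes, no saturated probes, and thresholds of 1.5-fold and 4-fold. A shift by 5 spike-in control probes within the linear range was added after the data had been seen. The work used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

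The procedure was tested on simulated data made from the day 0 arrays with added noise. The noise had the median spread between probes of 1 gene, 0.19 log2 units for LSK and 0.27 for CD45-negative cells. It was the same for dim and bright genes, while the 90th percentile of that spread was 0.545 and 0.777. At each fold, 100 genes were altered. At 2.5-fold, 95 of 100 genes were recovered for LSK and 84 of 100 for CD45-negative cells; at 4-fold, all 100 were recovered in both. Of the unaltered genes, 0 of 16263 and 5 of 14358 passed 2-fold. Of 100 lists of random genes, 4 and 2 lay outside the random range. This noise covers probes and spots only, not mice, sorting or labelling. The counts of unaltered genes past 2-fold follow from this noise level and do not give the rate of false differences on the real arrays.

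Left out were control spots, outlier spots and, for want of replicates, every analysis that needs a spread between animals. Probes that may also bind related genes, as in the immunoglobulin, T cell receptor, Klra, haemoglobin and kallikrein families, were kept, and their values may belong to a relative of the gene named.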

Results

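The series compared gene expression in blood stem and progenitor cells (LSK) and in CD45-negative marrow cells of healthy mice with the same populations 10 days after irradiation and transplantation, when the labels place the greatest proliferation of the stem cells. Its stated purpose was to find expression signatures of the niche cells during that proliferation. There was 1 array for each population and day. At day 0 and day 10, 54.5% and 56.6% of the 61307 probes were well above background for LSK cells, and 47.6% and 52.0% for CD45-negative cells. The number of genes detected was 17079 and 17515 for LSK cells and 15361 and 16587 for CD45-negative cells. Replicate spots of a probe within an array had an SD of 0.087 to 0.107 log2 units. No replicate array exists for any group in these files, so no difference below could be set against a spread between mice. The number of arrays limits the precision of every value.

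The first comparison asks how LSK cells of transplanted mice differ from those of healthy mice. Genes of mature cells were bright on these arrays. At day 0 the antibody gene Jchain stood at 7.60 and the basophil gene Prss34 at 7.47, with Kit at 5.04. At day 10 the neutrophil gene Chil3 stood at 5.94, with Kit at 4.65. Whether a difference lies in the stem and progenitor cells or in other cells of the sort was not tested. Antigen-presentation, macrophage and interferon-response lists were higher at day 10, mostly by less than 2-fold: the list of MHC class II genes had a median difference of 0.87, that of monocyte and macrophage markers 0.66 and that of interferon-response genes 0.62 (3 of 37 genes at least 2-fold higher). The size of the MHC class II and macrophage medians depends on the processing: under normexp background correction they were 0.26 and 0.34, and the MHC class II median was 0.63 with genes below background at their bounds. Markers of basophils and mast cells (median -1.11), plasma cells (-0.79), erythroid cells (-0.64) and T and NK cells (-0.50) were lower; under normexp the basophil and plasma cell medians were -0.69 and -0.51. Genes of DNA replication and the G1/S transition were level (median 0.01, 0 of 30 genes at least 2-fold apart). Only 238 genes were at least 2-fold higher and 438 at least 2-fold lower, together 4.11% of the 16463 genes measured on both arrays; under normexp these counts were 74 and 152.

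Among the interferon-response genes, Cxcl9, a chemokine for activated T cells, was at least 7.94-fold higher at day 10. Oas2, an antiviral enzyme (1.69), Ciita, the master regulator of MHC class II (1.11), and Oas1a (0.99) were also higher. H2-Aa, an MHC class II chain, was higher by 2.06 at its brightest probe and 0.68 at another, Cd74 by 1.0 and H2-Ab1 by 0.82. The macrophage markers Fcgr1 (1.90), Adgre1 (1.39) and Lyz2 (1.11) were higher, and Ms4a7 was at least 3.18-fold higher. The neutrophil list had a small median of 0.19, with 5 of 20 genes at least 2-fold higher; of its largest members, Chil3 was higher by 2.55, Ngp by 2.52, Ltf by 1.56 and Camp by 1.40. Fcgr4, an activating receptor for immunoglobulin G (2.42), Sirpb1a (2.5) and Cd300ld3 (2.25), both receptors of myeloid cells, were among the 10 genes with the largest differences. Chil3 and Ngp also belong to these 10. The others were the smooth muscle calponin Cnn1 (2.95), the BMP and nodal antagonist Dand5 (2.79), the secreted protease Htra3 (2.43, though -0.02 at its other probe), Fsip2l (2.37) and the stress-induced transcription factor Atf3 (2.33). The inflammatory cytokine list as a whole had a median of -0.24, with Il1b (1.48) and Lif (1.38) higher and Csf2 at least 2.28-fold lower and Icam1 at least 1.95-fold lower.

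Antibody genes were among the largest lower differences. Jchain, which joins secreted IgM and IgA, was 24.8-fold lower at day 10, Igh-6 12.4-fold, Igk-V21-4 11.4-fold and Ighv1-77 8.78-fold lower. Of the plasma cell list, Derl3 was lower by 5.90-fold and the receptor Tnfrsf17 at least 13.3-fold, while Sdc1 differed by -0.88. Cd8a (-3.05), Cd8b1 (-2.29) and Cd3d (-2.04), parts of the T cell co-receptor and receptor, were lower, and Gzma, a granzyme of killer cells, was higher (1.95). The basophil and mast cell genes Fcer1a (-2.15), Mcpt8 (-1.97), Prss34 (-1.89) and Cd200r3 (-1.54) were lower. Also in the lowest 10 were the transcription factor Etv1 (-3.40), the lectin Cd209d (-3.29), Asb2 (-4.59 at its brightest probe, 0.31 at another) and the kallikrein Klk1 (-3.27 and -0.33). The largest bounds rest on 1 probe each in most cases: Atp6v0e2 was at least 31.9-fold, Hoxc5 at least 13.1-fold and Cma1 at least 12-fold higher, and Vmn2r-ps38 at least 34.4-fold and Sytl2 at least 14.4-fold lower. A second probe of Atp6v0e2 was not above background.

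Lists of the erythroid and megakaryocyte lineages had lower medians, with few genes past 2-fold. The list of megakaryocyte-erythroid priming factors had a median of -0.54, with 2 of 18 genes at least 2-fold lower, and that of megakaryocytes and platelets -0.37, with 1 of 15 lower and 1 higher. Of the erythroid list, 3 of 18 genes were at least 2-fold lower. Pf4 was lower by 2.26-fold, Gata2 by 1.74-fold and Itga2b by 1.75-fold. The adhesion molecule Selp went the other way (2.15). Rhd (-1.46), Eraf, the haemoglobin chaperone (-1.31), Slc4a1 (-1.13) and Ermap (-0.95) led the erythroid list, and the haem biosynthesis list had a median of -0.26 with 0 of 22 genes at least 2-fold apart. The stem and progenitor list stayed inside the random range (median -0.12), although Mycn (-1.19) and Meis1 (-1.11) were lower; other probes of Mycn and Meis1 gave 0.23 and -0.30. Myeloid priming factors had a median of 0.00 and lymphoid priming factors of -0.10.

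Dividing and resting programmes differed little between the days. The list of G2/M and mitosis genes had a median of 0.18, small but outside the random range (percentile 99.5), and Ttk (0.62) and Bub1b (0.58) led it apart from Racgap1, whose probes disagreed (1.15 and -0.28). Mki67, the proliferation marker, differed by 0.16, and the cell cycle inhibitors Cdkn1a and Cdkn1c by 0.01 and -0.13. The quiescence list (median -0.11), the p53 targets (-0.05), homologous recombination (0.05), oxidative phosphorylation (0.07), glycolysis (-0.10) and apoptosis regulators (0.05) stayed inside the random range. Among single genes of these lists, the p53 target Pmaip1 was higher (1.41). The surface markers used for the sort were close to their day 0 levels, Kit with -0.39 and Ly6a with -0.11, and Ptprc, which encodes CD45, with 0.08. Of the niche genes, Cxcl12 was higher (1.01), Spp1 lower (-1.03), Vcam1 differed by -0.63 with 0.55 at another probe, Angpt1 by -0.01, and Kitl was not above background. The extracellular matrix list had a median of 0.30 with 4 genes higher and 4 lower by at least 2-fold, among them Col8a1 (at least 3.31-fold higher), Thbs1 (at least 3.01-fold higher), Lama5 (-1.45) and Sparc (-1.83, but -0.17 at its other probe). Its median was -0.070 under normexp background correction and -0.11 without a detection filter, so its direction depends on the processing.

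The median difference over all genes was -0.01 for LSK cells, and the shares of higher and lower genes depend on the scaling. Of the genes at least 2-fold apart, 35.2% were higher in the main setting, 45.7% after a median shift and 18.1% after a shift by spike-in controls.

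**Figure D1:**
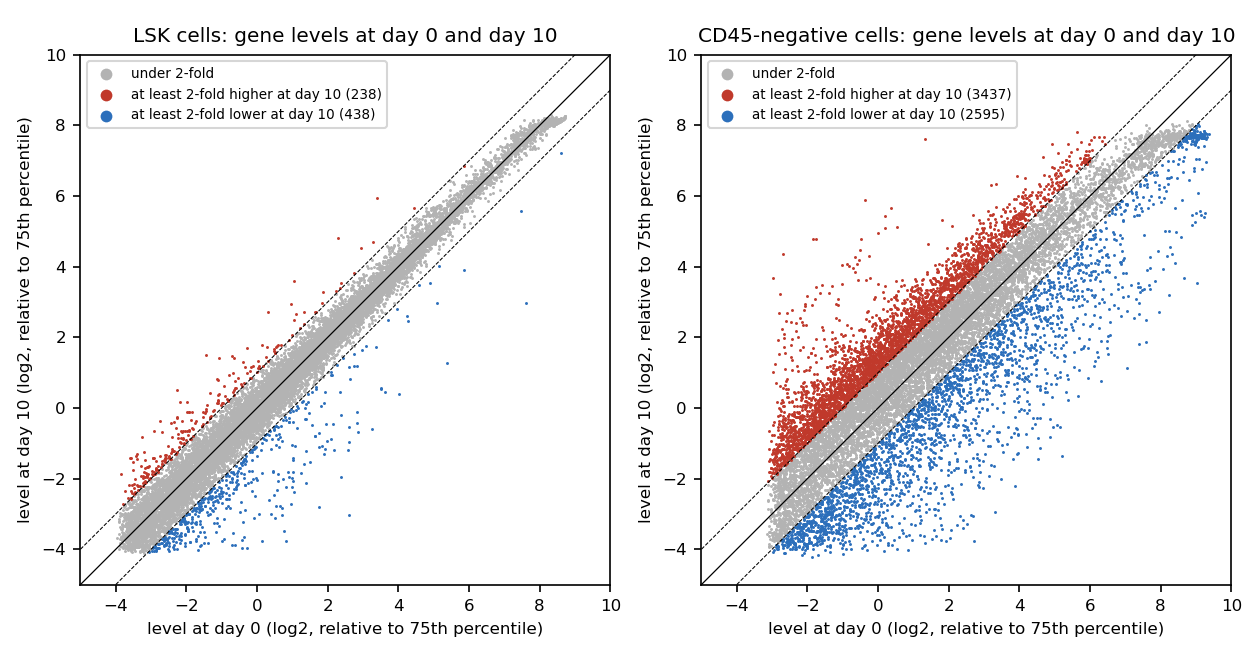
Levels of genes above background on both arrays at day 0 (horizontal axis) and day 10 (vertical axis), as log2 relative to the 75th percentile of the array, 1 point for each gene; dashed lines mark 2-fold. LSK genes lie close to the diagonal, with 238 higher and 438 lower, while CD45-negative genes spread widely, with 3437 higher and 2595 lower.

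The main comparison, for the niche, asks how CD45-negative marrow cells of transplanted mice differ from those of healthy mice. Red cell genes were lower: all 22 detected genes of the erythroid list were at least 2-fold lower at day 10, with a median of -4.31. Genes of stromal cells were lower too, with medians of -2.54 for CXCL12-abundant reticular cells, -2.33 for the extracellular matrix and -2.32 for osteoblasts. Lymphocyte lists were higher, with medians of 4.28 for T and NK cells, 2.79 for plasma cells and 1.62 for B cells. Sizes depend on the processing: under normexp the reticular cell, matrix and osteoblast medians were -1.49, -1.29 and -1.31, and that of T and NK cells 2.54. In all, 3437 genes were at least 2-fold higher and 2595 at least 2-fold lower, or 41.4% of the 14558 genes measured on both arrays.

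The T cell receptor chain Cd3d was 99.9-fold higher at day 10, Tcrb-V13 99.6-fold at its brightest probe (2.43 log2 units at its weakest), the lymphocyte membrane gene Ms4a4b 92.7-fold and Thy1 38.4-fold higher. The chemokine Ccl5 was 76.6-fold higher and its kin Ccl4 6.68-fold. The chemokine receptor Cxcr3 was higher by 5.02, and the NK cell receptors Klra7 and Klra16 by 5.22 and 4.97. Gzma was at least 150-fold, the interleukin receptor chain Il2rb at least 109-fold, Ifng, the interferon of T and NK cells, at least 67.9-fold and Cd8a at least 27.4-fold higher. Setting such genes at their bounds gave a T and NK cell median of 3.84, and medians of -2.15 for reticular cells, -1.64 for the extracellular matrix, -1.77 for platelet genes and -1.53 for fibroblast genes. Jchain (6.30), Ighv1-77 (4.99), Derl3 (4.12) and Sdc1 (3.31) were higher, as was Tnfrsf17 (at least 19.9-fold), and 8 of 8 plasma cell genes were at least 2-fold higher. The B cell genes Blk (2.80) and Ebf1 (1.91) were higher, with Pax5 at least 5.44-fold and Rag2 at least 4.41-fold higher. The inflammatory cytokine list had a median of 1.58, with Osm at least 6.63-fold higher.

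Myeloid lists varied. The neutrophil list had a median of 1.39, led by Ly6g (2.74), Padi4 (2.5), Mmp9 (2.46) and Ltf (2.09). The basophil and mast cell list had a median of 2.05 (0.80 under normexp), with Prss34 (2.74), Mcpt8 (2.40) and Hdc (2.05) higher and Il1rl1 (-3.80) lower. The monocyte and macrophage list stayed inside the random range (median 0.49): Itgam (2.32), Lyz2 (2.31) and Cd14 (2.26) were higher while the complement gene C1qb was lower (-2.93). Myeloid priming factors (median 1.33), with Id2 (2.54), Cd33 (2.42) and Csf3r (2.22), and lymphoid priming factors (median 1.56), with Notch1 (1.99), Ccr9 (2.23) and Lsp1 (1.97), were higher. Ptprc, the gene of the antigen used to exclude leukocytes, was above background at both days and stood at 3.10 at day 0 and 5.58 at day 10, which is 5.59-fold higher. Ly6a was higher by 3.24 and Kit by 0.42.

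Among red cell genes, Alas2, the first enzyme of haem synthesis in red cells, was 45.7-fold lower, and the membrane skeleton genes Epb42 and Sptb were 41.9-fold and 38.2-fold lower. The haem biosynthesis list had a median of -3.40, with Fech (-4.61), Abcb10 (-4.57) and Uros (-4.26). Some of the 10 largest lower differences are genes known from red cells, among them Tmcc2 (-5.97) and the transcription factor Sox6 (-5.73). Others were Aqp2 (-6.26), Sowaha (-6.10), Pdzk1ip1 (-5.92), Vav2 (-5.79), Mageb16 (-5.75), Ypel4 (-5.72) and Cyp4b1 (-5.70). The theta globin Hbq1a was at least 82.6-fold lower. Erythroid transcription and signalling followed: the megakaryocyte-erythroid priming list had a median of -3.07, with Tal1 (-4.51) and the erythropoietin receptor Epor (-4.30). Platelet genes were lower, with Ppbp at -5.69, Gp9 at -4.56, Vwf at -4.10 and Pf4 at -4.09 and a list median of -2.50. The stem and progenitor list was split and inside the random range (median 0.89, or 0.16 with genes below background at their bounds, and -0.36 to 1.35 over the alternatives; 6 genes higher and 4 lower), with Lmo2 (-3.61) and Gfi1b (-3.10) lower.

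Several genes of the stem cell niche were lower at day 10 relative to the other genes. Cxcl12, the chemokine that retains stem cells in the marrow, was 8.90-fold lower, Vcam1, an adhesion molecule, 5.22-fold, Gas6 5.26-fold and Spp1, osteopontin, 2.05-fold lower. After the spike-in shift, which adds 3.36 to every CD45-negative difference, Cxcl12, Vcam1, Gas6 and Spp1 would not be lower. Markers of several cell types differed in the same sort, and whether any 1 cell type made less of these transcripts was not tested. Kitl and Angpt1 were not above background at either day. The list of niche factors had a median of -0.32, inside the random range, with 9 of 22 genes at least 2-fold lower and 3 higher. The reticular cell genes Ebf3 (at least 13.3-fold), Cxcl14 (-3.59) and Serping1 (at least 9.22-fold) were lower. Col1a2 (-3.70), Col1a1 (-3.44), Col5a1 (-3.61), Mgp (-3.46), Dcn (-3.21) and the bone protein Bglap (-2.84) were lower, as was Pth1r, the parathyroid hormone receptor of bone cells (at least 6.35-fold). Fibroblast markers had a median of -2.12, which was -0.034 over the genes detected on all 4 arrays. Adipocyte markers had a median of -1.42, with the glucose transporter Slc2a4 (-4.54), Fabp4 (-2.40), Cfd (-2.37) and Adipoq (-1.85), and skeletal muscle markers of -2.54, with Pvalb (-3.30), Myh1 (-2.80) and Myl1 (-2.74). Endothelial markers (median -0.53), chondrocyte markers (-1.35), smooth muscle and pericyte markers (0.06), Schwann cell markers (-0.14) and the Wnt (-0.42) and Notch (0.80) pathways stayed inside the random range. Within them, the endothelial junction genes Cldn5 and Esam were at least 4.10-fold and 3.72-fold lower, the glial gene Gfap at least 49.3-fold lower, and Cnn1 was higher (2.60).

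Cell division genes were lower at day 10 relative to the other genes. After the spike-in shift the G2/M median was 1.78 and the G1/S median 2.52. Red cell genes were lower in the same sort, and whether any 1 cell type in it divided less was not tested. The G2/M and mitosis list had a median of -1.58, with 24 of 30 genes at least 2-fold lower, among them Ube2c (-2.43), Mki67 (-2.25), Prc1 (-2.23) and Cdc25c (-2.21). The DNA replication and G1/S list had a median of -0.84, with Ccne2 (-2.94), Tk1 (-2.21), Ccne1 (-2.12) and Orc1 (-2.03). The homologous recombination list followed (median -0.92), with Blm (-2.02) and Brca2 (-1.83). The cell cycle inhibitors Cdkn1a (1.42) and Cdkn1c were higher, the latter by 2.06-fold, and the quiescence list had a median of 1.1 with Nr4a2 (2.48) higher and Foxo3 (-3.17) lower. The p53 target list stayed inside the random range (median 0.66), with Pmaip1 (2.59) and Fas (1.93) higher.

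Signalling and metabolism differed as well. Adhesion and homing receptors had a median of 1.24, with the integrins Itgb7 (2.20), Itga6 (2.15) and Itgal (2.05). The TGF-beta and BMP list had a median of 1.22, with Bmp7 at least 7.24-fold higher. The immediate early and dissociation stress list had a median of 1.14, with Egr2 (2.71) and Nr4a1 (2.35) higher and Hspa1a (-2.52) lower. Whether handling of the samples differed between the days was not tested. The glycolysis list (1.09), with Slc2a1 (2.61), was higher. Ribosome biogenesis genes had a median of 0.82, although Odc1 was lower (-2.74). The interferon list had a median of 0.80 with opposed members: Ifit3 (3.72) and Zbp1 (2.33) were higher, and Rsad2 (-4.16) and Isg15 (-2.87) lower. The oxidative stress list had a median of -0.65, with the glutathione and quinone enzymes Gclm (-4.32) and Nqo1 (-3.75). MHC class II genes (median 0.99), apoptosis regulators (0.55), cholesterol synthesis (0.19), oxidative phosphorylation (-0.06) and housekeeping genes (0.07) were inside the random range. Among housekeeping genes the transferrin receptor Tfrc (-3.24), also a red cell gene, was lower.

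The median difference over all genes was 0.19 in these cells, so a list near that value did not differ from the array as a whole. Of the genes at least 2-fold apart, 57.0% were higher in the main setting, 76.4% after a median shift (median of all genes 0.65) and 99.2% after the spike-in shift (median of all genes 3.55). Under the spike-in shift the T and NK cell and erythroid lists keep their signs, while the stromal, muscle, platelet and cell division lists become higher at day 10, so the lower values of those lists are relative to the other genes. Of the bounds, Atoh7 (at least 1740-fold higher) rests on 1 of its probes, the other being below background, and Vmn1r195 and Taar4 (at least 72.1-fold and 70.1-fold lower) rest on 1 probe each. Xist, the RNA of the inactive X chromosome, was at least 125-fold higher. The brightest genes were saturated on 1 or both arrays; without saturated probes 3433 genes were higher and 2442 lower.

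**Figure D2:**
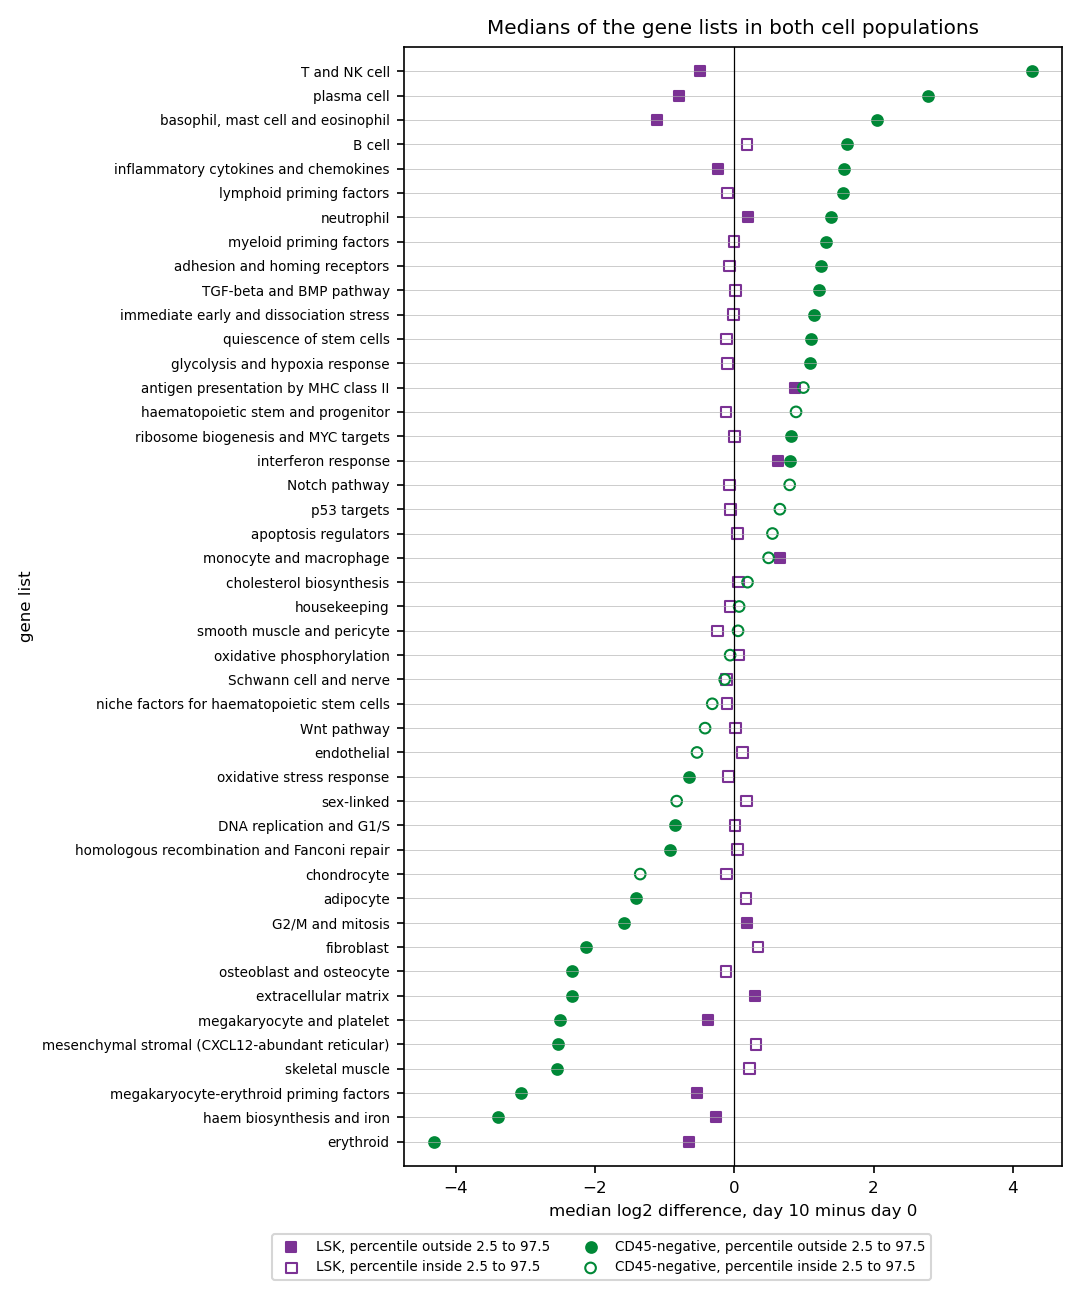
Median log2 difference, day 10 minus day 0 (horizontal axis), of each gene list (vertical axis) in LSK cells (squares) and CD45-negative cells (circles); filled points lie outside the range of random lists. T and NK cell genes are at 4.28 and erythroid genes at -4.31 in CD45-negative cells, while all LSK medians lie between -1.11 and 0.87; under the spike-in shift 12 of the 14 filled lower CD45-negative medians become higher.

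The next question is how far the populations shared their differences. Among 14236 genes measured on all 4 arrays, 79 were at least 2-fold higher in both, where 40.6 would be shared by chance, and 95 were lower in both, where chance gives 45.4. In the opposite sense, 111 were lower in LSK and higher in CD45-negative cells (63.2 by chance), and 30 were higher in LSK and lower in CD45-negative cells (29.2 by chance). Under normexp correction 39 were higher in both (14.1 by chance) and 21 lower in both (14.5). After the spike-in shift 93 were higher in both (95.3 by chance), so that excess is absent there, and 22 were lower in both (2.09). With no detection filter, 216 were higher in both, where chance gives 239. The number lower in LSK and higher in CD45-negative cells was 71 under normexp (22.6 by chance) and 57 at the 4-fold threshold (2.77 by chance). After the spike-in shift it was 313, below the 363 given by chance, and with no detection filter 309, below 321. The day 10 difference was at least 4-fold apart between the populations for 1683 genes, above in CD45-negative cells for 686 and below for 997, and this count of 1683 was 965 under normexp and 12745 after the spike-in shift. Across genes, which are not independent, the Pearson correlation of the differences was -0.01 and the Spearman correlation 0.06. Shared higher genes include Cnn1, Chil3, Ngp, Sirpb1a, Htra3, Fcgr4 and Atf3 from the LSK comparison, with 2.60, 1.07, 1.86, 2.06, 1.36, 1.99 and 1.16 in CD45-negative cells. Shared lower genes include Sox6, at -1.62 in LSK and -5.73 in CD45-negative cells, and Sparc, at -1.83 and -3.22, though Sparc is near its day 0 level at another LSK probe and is not lower in CD45-negative cells after the spike-in shift.

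The remaining comparisons describe the identity of the sorted populations. At day 0, LSK cells were higher in stem and progenitor genes (median 3.52 over CD45-negative cells, with 14 of 19 genes at least 2-fold higher), and in basophil and mast cell genes (5.60, or 3.54 with genes below background at their bounds). CD45-negative cells were higher in erythroid genes (median -6.22, 22 of 22 genes), haem biosynthesis (-4.65), reticular stromal genes (-3.38, or -2.06 with bounds) and G2/M genes (-1.84, 29 of 30 genes). The spike-in shift adds 1.74 to each of these differences and takes the G2/M median close to 0. Among the largest differences were Prss34 (7.64), Mcpt8 (7.15), Jchain (6.27), Gata2 (6.22) and Cpa3 (6.04) on the LSK side, and the fatty acid receptor Cd36 (-8.65), Rsad2 (-7.98), Rhag (-7.96) and Tmcc2 (-7.92) on the CD45-negative side. In all, 3181 genes were at least 2-fold higher and 2582 lower in LSK cells, of 14600. Of the genes apart, 55.2% were higher in LSK cells, 45.1% after the housekeeping shift and 95.2% after the spike-in shift, where the median of all genes was 1.83.

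At day 10 the stem and progenitor list was still higher in LSK cells (median 2.21, 11 of 20 genes), and the erythroid list lower (-2.92, 20 of 22 genes). The spike-in shift adds -1.78 to each difference between the populations at day 10, which takes away most of the stem and progenitor median. The reticular stromal list was no longer outside the random range (-0.47). The T and NK cell list was 2.51 higher in LSK cells at day 0 and stood at -2.48 at day 10 (1.83 at day 0 with bounds), and the plasma cell list at 2.06 and -2.71. LSK cells were higher in Hlf (5.71), of the stem and progenitor list, and Cd34 (5.28), of the adhesion and homing list. Plppr3 (4.98), Pdgfrb (4.95) and Tfec (4.84) were also higher in LSK cells. CD45-negative cells were higher in the B cell gene Fcrla (-6.82), Col5a3 (-6.19, but -0.91 at another probe), the neutrophil genes Mmp9 (-6.02) and Stfa2l1 (-6.01), and Rgs16 (-5.93). In all, 1758 genes were at least 2-fold higher and 2014 lower in LSK cells, of 15898. Of the genes apart, 46.6% were higher in LSK cells, 33.8% after cyclic loess, 17.96% after a median shift (median of all genes -0.41) and 0.71% after the spike-in shift (median of all genes -1.78).

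**Figure D3:**
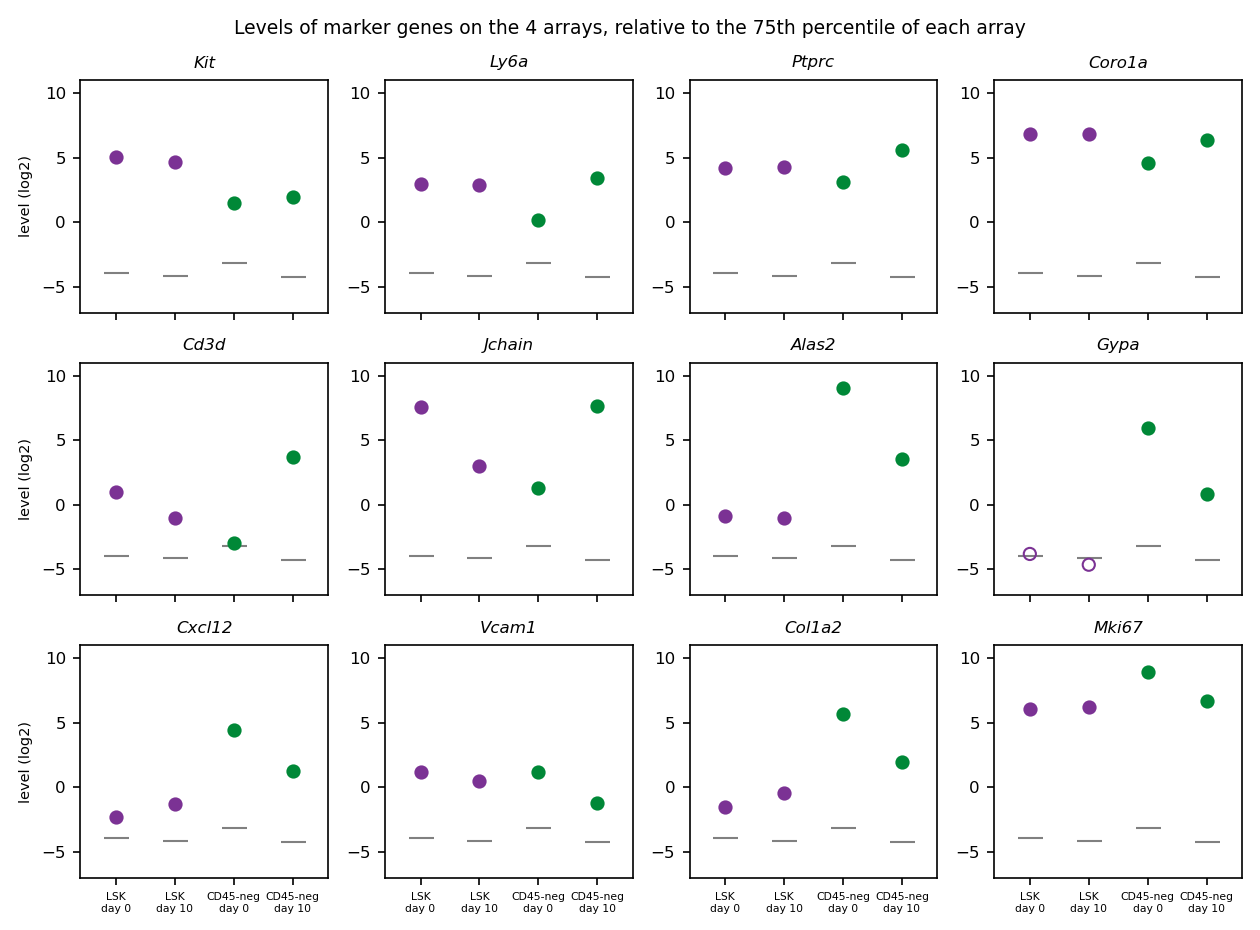
Levels of 12 marker genes (vertical axes, log2 relative to the 75th percentile of the array) on the 4 arrays, 1 point for each array; open points were not well above background and grey bars mark the lowest level called above it. Kit is higher in LSK cells at both days and Ly6a at day 0 only, and in CD45-negative cells Alas2, Cxcl12 and Col1a2 stand lower and Cd3d and Ptprc higher at day 10; after the spike-in shift, which adds 3.36 to every CD45-negative difference, Cxcl12 is no longer lower.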

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

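The tests in this part were chosen only after the result was seen, apart from the pan-leukocyte test of the first pattern. The values that follow were singled out because the day 10 difference had opposite signs in LSK and CD45-negative cells in the main setting, or because the probes took no part in the gene comparisons. With 1 array in each group, the differences between the populations were not tested.

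The lists that follow had opposite signs in the populations in the main setting, while others, such as the neutrophil list, had the same sign. The median of the T and NK cell list was -0.50 in LSK cells and 4.28 in CD45-negative cells. The plasma cell list had -0.79 and 2.79, the basophil, mast cell and eosinophil list -1.11 and 2.05, and the inflammatory list -0.24 and 1.58. In the other direction, the G2/M and mitosis list had 0.18 in LSK and -1.58 in CD45-negative cells, and the extracellular matrix list 0.30 and -2.33. The opposite signs of these 2 lists depend on the processing: after the spike-in shift both were positive in both populations (0.01 and 1.78 for G2/M, 0.13 and 1.03 for the matrix), and the LSK matrix median was -0.07 under normexp and -0.11 with no detection filter. Among single genes, Jchain differed by -4.63 in LSK and 6.30 in CD45-negative cells, Igh-6 by -3.63 and 4.73, and Ighv1-77 by -3.13 and 4.99. Cd3d differed by -2.04 and 6.64, Tcrb-V13 by -1.16 and 6.64, Klra7 by -1.08 and 5.22, Asb2 by -4.59 and 3.54, and Klk1 by -3.27 and 1.30. Dand5 alone of these genes was higher in LSK (2.79) and lower in CD45-negative cells (-3.61). Immunoglobulin, T cell receptor and Klra probes can also bind related genes. The LSK values of Asb2 and Klk1 rest on 1 probe each, since another probe gave 0.31 for Asb2 and -0.33 for Klk1.

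The first pattern is the opposite course of lymphocyte and red cell genes in the CD45-negative sort. A different scaling factor between the arrays is excluded, since it moves all lists alike and the T and NK cell median stood 8.58 log2 units above the erythroid median. A lower share of erythroid cells alone is excluded too, because it raises all other cell types alike and the T and NK cell median stood 6.81 above the mesenchymal stromal median. Leukocytes in the day 10 sort remain a candidate explanation: the median of 13 pan-leukocyte genes, in none of the other lists, was 1.78 higher (12 of 13 at least 2-fold, percentile 99.99), with Coro1a going from 4.54 to 6.33, Arhgdib from 4.71 to 6.61 and Lcp1 from 3.30 to 5.34, while LSK cells, which express all 13 as the day 0 sort did, differed by 0.08. Their median in LSK cells minus the CD45-negative sort was 1.35 at day 0 and -0.22 at day 10. Ptprc stood at 5.58 in the day 10 sort and at 4.255 in day 10 LSK cells. The day 10 sort thus carried pan-leukocyte transcripts at about the level of LSK cells, relative to each array. The labels call the sort both CD45.1-negative, which would keep donor CD45.2 leukocytes, and CD45-negative, which would remove them; which leukocytes were present, and whether irradiation or transplantation altered the stromal cells themselves, was not tested.

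The second pattern lies in the noncoding-transcript probes, which the gene comparisons did not use. In LSK cells 172 were at least 2-fold higher and 376 lower of 8950 measured, and in CD45-negative cells 420 were higher and 2821 lower of 7025; after the spike-in shift, tried later, 6564 of these would be higher and 53 lower, so the lower values are relative to the array as a whole. A difference between the arrays that depends on signal level is excluded as the whole cause, since the noncoding median lay below the gene median in 20 of 20 bins of equal level, by 0.12 to 1.25 log2 units. A raised floor on the dimmer day 0 array is excluded as well: among 2149 noncoding probes above the 75th percentile on both arrays, 98 were higher and 833 lower, so that 89.5% of those apart were lower, against 42.9% of gene probes. A lower share of unprocessed or nuclear RNA relative to gene transcripts in the day 10 cells, as a different cell makeup could bring, stays open and was not tested.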

How the results depend on the processing

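Only the spike-in shift was chosen after seeing the data. No paired analysis was possible because each group has 1 array and the labels match no day 10 sample to a day 0 sample, and leaving out replicates was not possible. Over all alternatives, 108 of 163 gene counts stayed within 1.5 times the main count, and 55 moved. Apart from the spike-in shift, 845 of 990 list medians stayed within the SD of matched random lists, 143 moved, and 2, of 1 LSK list outside the random range, changed sign. Lists inside that range, whose direction is not read, changed sign more often: 38 of 341 values over 15 of 31 LSK lists, and 19 of 176 values over 9 of 16 CD45-negative lists. Of 3271 values of named genes, 2777 stayed within the spread between probes and 494 moved, with 0 sign changes among genes at least 2-fold apart. These do not include the spike-in shift, under which 53 of 157 such CD45-negative genes and 0 of 67 LSK genes would change sign. Detection on all arrays and leaving out saturated probes keep a gene's main value by construction, and the deposited table differs from it by nearly a constant. The genes with the largest differences had also been chosen for the same direction under normexp, quantile, cyclic loess and the mean of probes. The tallies of named genes therefore overstate their stability. All 15 higher and 14 lower CD45-negative lists outside the random range kept their sign under the alternatives fixed beforehand; the erythroid median ranged from -4.66 to -3.74 and the T and NK cell median from 2.54 to 4.74. Sizes were less stable: 13 of these 29 medians came nearer to 0 by over 1.5 times under at least 1 alternative. The fibroblast median came to -0.034 over genes detected on all arrays. Under normexp the basophil list came to 0.80, inflammatory 0.73, quiescence 0.46, TGF-beta 0.62, megakaryocyte -1.28, mesenchymal stromal -1.49, osteoblast -1.31, matrix -1.29 and T and NK cell 2.54; under the median shift, G1/S came to -0.38, homologous recombination -0.45 and oxidative stress -0.18. In LSK cells, 5 of 6 higher and 8 of 8 lower lists kept theirs, and 7 of these 14 came nearer to 0 by over 1.5 times: under normexp MHC class II to 0.26, monocyte and macrophage 0.34, basophil -0.69, plasma cell -0.51 and megakaryocyte-erythroid priming -0.35, and with the mean over probes inflammatory to -0.047. The exception in sign, the last of these 7, was the extracellular matrix, at -0.070 under normexp correction and -0.11 with no detection filter.

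Counts that moved are given as higher and lower. Normexp gave 74 and 152 for LSK, 970 higher for LSK against CD45-negative at day 10, 39 higher and 21 lower in both populations, and 965 apart 4-fold. The median shift gave 5477 and 1689 for CD45-negative, 847 and 3870 for LSK against CD45-negative at day 10, and 127 higher in both. With no detection filter there were 1458 and 1955 for LSK, 10879 lower for CD45-negative, 5292 and 5699 between populations at day 0, 4866 higher at day 10, 216 and 996 in both, and 4962 apart. Detection on at least 1 array gave 655 and 849 for LSK, 4870 higher between populations at day 0, 3012 at day 10, and 178 and 166 in both. Detection on all 4 arrays gave 266 lower for LSK. These filters add or remove dim genes by construction. The 1.5-fold threshold gave 1027 and 1226 for LSK, 5260 higher for CD45-negative, 4831 and 3951 at day 0, 3584 and 3874 at day 10, and 366 and 318 in both. The 4-fold threshold gave 20 and 98, 603 and 1030, 887 and 1054, and 327 and 520 for the 4 comparisons in that order, and 4 and 1 in both. For normexp and the scalings, the cause was not tested.

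The spike-in shift gave 138 higher for LSK, 13808 and 116 for CD45-negative, 11253 and 565 at day 0, 96 and 13339 at day 10, 22 lower in both, and 12745 apart. The excess over chance of genes higher in both was lost after this shift (93, with 95.3 by chance) and with no detection filter (216, with 239), and that of genes lower in both at 4-fold (1, with 4.47 by chance). That of genes lower in LSK and higher in CD45-negative cells was lost after this shift (313, with 363) and with no detection filter (309, with 321). It stood at 4-fold (57, with 2.77). The cause of these losses was not tested. CD45-negative medians that turned positive were megakaryocyte 0.86, mesenchymal stromal 0.82, osteoblast 1.04, adipocyte 1.94, fibroblast 1.24, skeletal muscle 0.82, G1/S 2.52, G2/M 1.78, homologous recombination 2.44, matrix 1.03, oxidative stress 2.71 and megakaryocyte-erythroid priming 0.29; the erythroid (-0.95) and haem (-0.04) lists stayed lower. The array's 75th percentile minus the spike-in median was -3.68 and -0.33 for CD45-negative cells at day 0 and day 10, against -1.94 and -2.11 for LSK. Whether more RNA, more label or less spike-in went on the day 10 array cannot be read from the files. Signal over background limits dim genes, most on the dimmest array (CD45-negative day 0, 47.6% of probes above background).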

Other observations

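All tests in this part were chosen only after the result was seen. More genes shared their direction in both populations at day 10. Apart from Il1b and Pmaip1, which the naming rule picks, they were chosen here after their values were seen, and values are given first for LSK and then for CD45-negative cells. Socs2, a brake on cytokine signalling, was higher by 2.0 and 2.86, Med13l by 1.64 and 2.38, the antiviral editing enzyme Apobec3 by 1.44 and 1.47, the cytokine Il1b by 1.48 and 2.38, and the cell death gene Pmaip1 by 1.41 and 2.59. Shared lower genes were the sulfotransferase Chst10 (-2.27 and -4.70), the growth factor receptor regulator Lrig1 (-1.96 and -3.71), the collagen chaperone Serpinh1 (-1.65 and -3.04) and the procollagen protease Bmp1 (-1.61 and -2.83), of which Serpinh1 and Bmp1 would not be lower in CD45-negative cells after the spike-in shift.

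Some genes were higher in LSK cells and lower in CD45-negative cells at day 10. In the main setting their number was about what chance gives (30, with 29.2 by chance). Under normexp it was 5, with 9.09 by chance, and with no detection filter 732, with 539 by chance. Among the 30 were Cd36 (1.99 and -5.69), Col1a2 (1.08 and -3.70) and Cxcl12 (1.01 and -3.15). The small RNA genes Rmrp (1.54 and -4.21), Rpph1 (1.23 and -2.21), Snord15a (1.01 and -3.91) and Terc, the telomerase RNA (1.11 and -1.21), were others. After the spike-in shift, which raises each CD45-negative difference by 3.36, Cxcl12, Rpph1 and Terc would be higher in both. Labelling was primed with oligo-dT, so which forms of the small RNAs these probes measured is not known.

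Xist, made from the inactive X chromosome of female cells, was not above background in either population at day 0 and was at day 10, in samples that also gave signal for genes of the Y chromosome. Cross-hybridisation at a single probe is excluded for the CD45-negative sort: 4 of 4 Xist probes were at least 2-fold higher, by at least 125-fold, 9.49-fold, 7.58-fold and 27.2-fold. If the day 10 sample held cells of both sexes in place of male cells only, the Y-linked genes would be lower, and their median was -1.02, at percentile 5.19 of random lists, with Kdm5d higher; in LSK cells it was 0.10 (percentile 69.5). The sign depends on the scaling, since after the spike-in shift, tried later, the CD45-negative median would be 2.34. The Y-linked median cannot decide the question, since it rests on only 4 genes, depends on the scaling, and markers of several cell types differed as well. Xist (3.81) and all 4 Y-linked genes were above background together on the day 10 CD45-negative array, as cells of both sexes would give. Cells of both sexes may thus have been present, but the labels give no sex for donors or recipients to check this.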
